A study of Mus musculus with 6 samples.

How the data were processed

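The 3′ ends of polyadenylated RNA were sequenced in V6.5 mouse embryonic stem cells, a pluripotent line of mixed C57BL/6 and 129 background. There were 6 libraries in 3 groups of 2: untreated cells, cells given a scrambled antisense morpholino oligonucleotide (AMO), and cells given an AMO against U1. U1 is the small nuclear ribonucleoprotein that recognises 5′ splice sites and is known to suppress cleavage and polyadenylation at sites inside transcribed regions. Per the labels' protocols, poly(A)-selected RNA was fragmented with RNase T1, reverse transcribed, size-selected on a gel, circularised, amplified by PCR and sequenced on an Illumina HiSeq. No molecular identifiers are described, so intervals and floors given here cover counting error only.

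Per the submitters' processing notes, the tools were cutadapt and Bowtie and the genome build was mm9; their versions are not given in the sources used here. Each library was deposited separately as a list of stranded cleavage positions with whole-number read counts, not normalized. Each position also carries a deposited hexamer of the poly(A) signal type (36 kinds), the distance from that hexamer to the position (6 to 40 nt) and a whole number from 0 to 10. The meaning of this last number is not given in the sources used here. It changed by at most 1 between adjacent positions. Every listed position had a hexamer, so positions without one were not analysed here. Shares of hexamers refer to the listed positions, or to clusters of them, outside chromosome M. How the positions were filtered is not given in the sources used here.

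Positions from the 6 libraries were pooled (2341170 distinct positions), and same-strand positions at most 24 nt apart were joined into 931826 clusters, whose median width was 1 nt. Reads were summed per cluster and library. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization and filterByExpr, which kept 80049 clusters. All 6 libraries entered one fit with the 3 groups, and Benjamini-Hochberg adjusted p-values under 0.05 were called. Standard errors were derived from the log2 fold change and its F statistic. Levels are CPM, reads scaled to the total of each library, computed here from the deposited counts. DESeq2 1.42.0 served as an alternative. Other values were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

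The samples, tests and alternative settings were fixed, other than those said to be added, before the data were examined. For clusters, the rule for naming was the 5 highest and 5 lowest log2 fold changes among called clusters with a mean of at least 20 CPM over the 4 libraries compared. Exact permutation tests were two-sided, and 2 libraries against 2 cannot go below p = 0.333. For median folds of raised sets, control groups with fewer than 3 counts were set to a floor of 3. For named clusters this floor was used only where the control group had no reads, and other ratios used the counts themselves. Intervals of shares are 95% Wilson intervals.

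Read names in the files showed how the libraries were sequenced. Replicate 1 of the scrambled AMO and of the U1 AMO shared one run and lane. Replicate 2 of both shared another run, in separate lanes. Each untreated library came from a run of its own. The deviations of the scrambled AMO and U1 AMO libraries from their group means correlated at r = 0.80 within a replicate number, across 29450 clusters, which are not independent replicates. Within these 4 libraries the replicate number and the run are the same term. A fit of the 4 libraries with this term was therefore added after seeing the data. It leaves 1 residual degree of freedom, so its p-values lean on the spread shared across clusters. Untreated cells cannot be separated from their runs.

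The test was checked on simulated counts with 200 clusters changed by known folds, drawn from clusters with a mean of at least 1 CPM. The counts were drawn with the spread that the same design estimated, so the check takes that spread as true. It cannot show whether the small spread of the fit with run as a term is right. The spread shared across clusters (common dispersion) was 0.0244 in that fit and 0.329 in the main one. For U1 AMO against scrambled AMO, the main design recovered 0% of 4-fold, 70% of 16-fold and 96% of 64-fold changes among 80049 clusters. The fit with run as a term recovered 50% of 2-fold and 100% of 4-fold changes among 68821 clusters. The clusters that rose in this fit had a median of 0.425 CPM over the 6 libraries, so these rates do not cover most of them. Scrambled AMO against untreated gave 4% of 4-fold and 64% of 16-fold changes. U1 AMO against untreated gave 4% and 74%.

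For the arrangement of clusters, raised clusters were compared with uncalled clusters matched on mean CPM (up to 5 per raised cluster) by Fisher's exact test; clusters are not replicates. The comparison of distinct positions at equal depth thinned every library to 15752080 reads, with 20 seeded draws. Profiles around strong clusters were added after seeing the data. They left out chromosome M and were scaled to the reads outside it. The arrangement of clusters was also taken outside chromosome M. No genome or annotation of build mm9 was used here, and coordinates were not converted. Planned results by gene, gene list, promoter window, read class and distance from the transcription start were therefore not run, and clusters are given by position alone, without gene names.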

Results

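Cleavage and polyadenylation sites were mapped by 3′ end sequencing in mouse embryonic stem cells with and without inhibition of U1. The libraries held 38569397 and 60473882 reads from untreated cells, 26846406 and 62257923 with the scrambled AMO, and 15752080 and 57925358 with the U1 AMO (replicates 1 and 2). They covered 744611 and 500472 distinct positions in untreated cells, 804486 and 1039972 with the scrambled AMO, and 683584 and 1193338 with the U1 AMO. In the main test the p-values rest on a spread estimated jointly over all groups, untreated cells included, with 2 libraries per group. That test did not pair the scrambled AMO and U1 AMO libraries of the same run. Fisher's exact p-values are over clusters and do not measure the spread between libraries.

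The first comparison asked where cleavage changes when U1 is inhibited, with the scrambled AMO as the control. A set of 533 cleavage clusters rose with the U1 AMO, and no cluster passed the test for a fall (edgeR quasi-likelihood test, 80049 clusters). The raised clusters were close to silent in the controls. The test favours such clusters, since the main design recovered 0% of 4-fold and 70% of 16-fold changes in simulated counts. Together the 533 took 0.867% and 0.715% of reads in the U1 AMO libraries. Their shares were 0.0380% and 0.0320% with the scrambled AMO and 0.0211% and 0.0242% in untreated cells. The median rise was 89.5-fold from pooled counts, with the scrambled AMO at no fewer than 3 counts, and 204 clusters were at or under that floor. In 76 of the 533 clusters neither scrambled AMO library had a read.

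Among the 35 raised clusters with a mean of at least 20 CPM, the strongest rise was at chr11:69391758-69391782 on the minus strand (mm9). There the U1 AMO libraries had 791 and 2124 reads and the scrambled AMO libraries 0 and 1. The ratio of pooled levels was 3525 (95% counting interval 632 to 139291), the adjusted p was 0.0212 in edgeR, and the untreated libraries had no reads. At chr10:88288888-88288904 on the minus strand, 745 and 2409 reads with the U1 AMO stood against 2 and 0, a ratio of 1907 (528 to 15755). On the plus strand, chr2:128929801-128929811 reached 58.6 ± 7.18 CPM (SD, n = 2) with the U1 AMO against 0.0694 ± 0.00725 with the scrambled AMO. The cluster at chr5:143723224-143723247 (plus strand) had 60.2 ± 28.4 CPM against 0.0906 ± 0.0826 (SD, n = 2). The cluster at chr7:133643457-133643483 (minus strand) had 40.6 ± 3.66 CPM against 0.080 ± 0.0449 (SD, n = 2). The hexamer at the strongest position was AATAAA in the chr11 and chr5 clusters, ATTAAA in the chr2 and chr7 clusters and AATATA in the chr10 cluster.

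**Figure D1:**
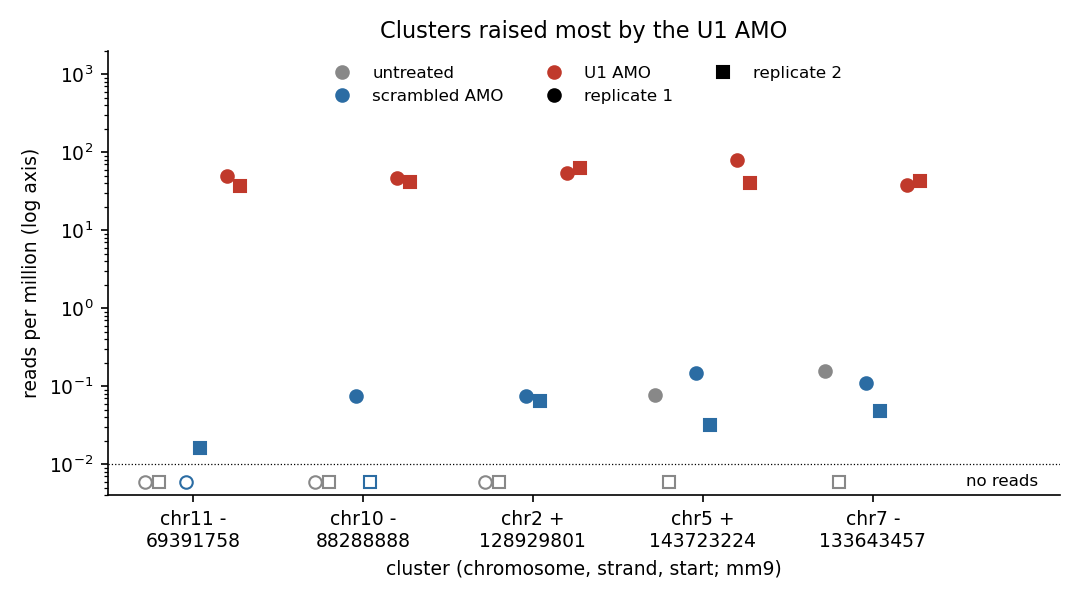
CPM (log axis) in each of the 6 libraries at the 5 clusters with the highest fold change for U1 AMO against scrambled AMO; circles are replicate 1, squares replicate 2, and open symbols below the dotted line mark libraries without reads. The U1 AMO libraries lie between 36.7 and 80.3 CPM, and the scrambled AMO libraries lie at 0.149 CPM or below.

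With the sequencing run as a term in a fit of the 4 AMO libraries, chosen after seeing the data, 9199 clusters rose and 1571 fell among 68821, and the 533 clusters were among those called. The median rise was 10.5-fold from pooled counts with the same floor, and 3997 of the 9199 were at or under it. The clusters that rose took 10.1% and 8.18% of U1 AMO reads against 4.85% and 4.24% with the scrambled AMO. The clusters that fell were abundant, with a median of 19.1 CPM, and their median fall was 1.54-fold. Of the 1571, 158 (10.1%) had at most 3 reads in U1 AMO replicate 1, the shallowest library. The groups did not overlap at 1082 (68.9%) of the falls and at 8833 (96.0%) of the rises.

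The 5 largest falls under the naming rule came mostly from the run of replicate 1; in replicate 2 the falls were smaller at 4 of them, and the level at chrX:119879536 was slightly higher with the U1 AMO. At chr4:68759744-68759745 (plus strand) replicate 1 had 7.71 CPM with the scrambled AMO and 0.127 with the U1 AMO, and replicate 2 had 73.9 and 40.1. At chr2:76889896-76889902 (minus strand) replicate 1 had 12.6 and 0.254 CPM, and replicate 2 had 89.5 and 86.4. The clusters at chr4:40290052-40290053 (minus), chrX:119879536-119879549 (minus) and chr16:11262290-11262293 (plus) had 0.190, 1.33 and 0.317 CPM in U1 AMO replicate 1, against 10.1, 31.1 and 5.59 with the scrambled AMO of the same run. In replicate 2 they had 65.0, 56.5 and 27.0 CPM against 106.8, 54.9 and 48.6. A further condition, set after values were seen, was that the groups did not overlap. The largest fall among such clusters with a mean of at least 20 CPM was at chr8:67654777-67654787 (minus strand). It had 46.8 ± 14.1 CPM with the U1 AMO and 107.0 ± 55.8 with the scrambled AMO (SD, n = 2). Replicate 1 had 146.4 CPM with the scrambled AMO and 36.9 with the U1 AMO, and replicate 2 had 67.6 and 56.8. This fall too came mostly from replicate 1, and the untreated libraries had 492.4 and 75.4 CPM. The log2 fold change of this cluster in edgeR was -1.12 ± 0.22 (SE), with an adjusted p of 0.000222. These 6 clusters were not called in any fit without run as a term. With scrambled AMO replicate 2 left out of the 6-library fit, the log2 fold changes of the 5 named first turned to rises of 0.05 to 1.94. That fit has no run term and compares libraries across runs, so it does not measure a fall within a run.

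The count of calls varied with the libraries and the fit. Without scrambled AMO replicate 2 no cluster was called (4612 at an unadjusted p under 0.05), without scrambled AMO replicate 1 there were 113, without U1 AMO replicate 2 there were 66 and without U1 AMO replicate 1 there were 1157, all of them rises. Leaving an untreated library out of the shared fit, chosen after seeing the data, gave 2760 rises without replicate 1 and 2951 without replicate 2, and no falls. Adding the replicate number as a block to all 6 libraries also left 0 calls by edgeR (5676 at an unadjusted p under 0.05), and DESeq2 without a block called 3129 rises and 0 falls.

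Raised clusters lay mostly upstream of a stronger site, meaning one with a higher mean CPM over the 6 libraries. Matching used the same mean, which includes the near-silent controls. For the 533 its median was 2.69 CPM, against 8.76 and 6.92 in the U1 AMO libraries. Strength within the U1 AMO libraries alone was not examined. Of the 533, 77.5% had a stronger same-strand cluster within 50 kb downstream, against 50.8% of uncalled clusters of matched CPM (Fisher's exact test over clusters, p = 2.99e-31), and the median distance to it was 13.3 kb against 2.87 kb. A cluster on the opposite strand within 5 kb of the 5′ side, the divergent arrangement, was found at 24.2% against 11.8% (Fisher's exact p = 1.18e-12). The convergent arrangement was less frequent, at 6.75% against 19.9% (Fisher's exact p = 3.31e-15). With a limit of 10 kb the downstream share was 30.8% against 33.0% (Fisher's exact p = 0.336), and with a limit of 2 kb the divergent share was 8.44% against 6.90% (p = 0.231), so neither difference held at the shorter range. Without U1 AMO replicate 2, which left 66 raised clusters, the divergent share was 36.4%, and the convergent share was 3.03%. Clusters that rose in the fit with run as a term had divergent partners at 15.9% against 10.3% within 5 kb, and at 5.12% against 5.57% within 2 kb (Fisher's exact p = 0.185).

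**Figure D2:**
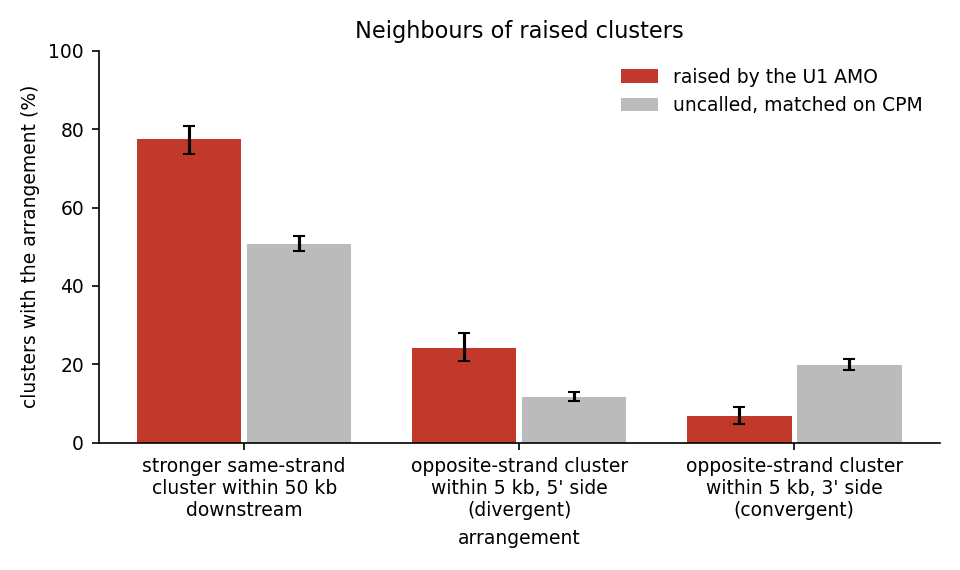
Share of clusters (percent) with each arrangement among the 533 clusters raised by the U1 AMO and 2665 uncalled clusters matched on CPM; error bars are 95% Wilson intervals over clusters. Raised clusters stand at 77.5%, 24.2% and 6.75%, and matched clusters at 50.8%, 11.8% and 19.9%.

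Reads on the same strand as strong sites were higher upstream of them with the U1 AMO, beyond 2 kb, and by less downstream. In the 10 to 50 kb upstream of 6433 clusters with at least 10 CPM and no stronger same-strand cluster within 50 kb, same-strand reads summed over these windows came to 54717 ± 3219 CPM with the U1 AMO, 48507 ± 1345 with the scrambled AMO and 47794 ± 134 in untreated cells (SD, n = 2). The ratio of U1 AMO to scrambled AMO was 1.15 within the run of replicate 1 and 1.10 within that of replicate 2. The exact permutation p was 0.333, the smallest this design allows. On the downstream side the same-strand ratios were 1.23 and 1.08 at 5 to 10 kb, against 1.24 in both runs at that distance upstream, and 1.04 in both runs at 10 to 20 kb, against 1.24 and 1.17 upstream. The difference between the sides was not tested. Of 6396 strong clusters with such reads, 53.9% had a higher upstream level with the U1 AMO in both runs and 16.3% a lower one in both. Windows of different strong clusters can overlap.

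**Figure D3:**
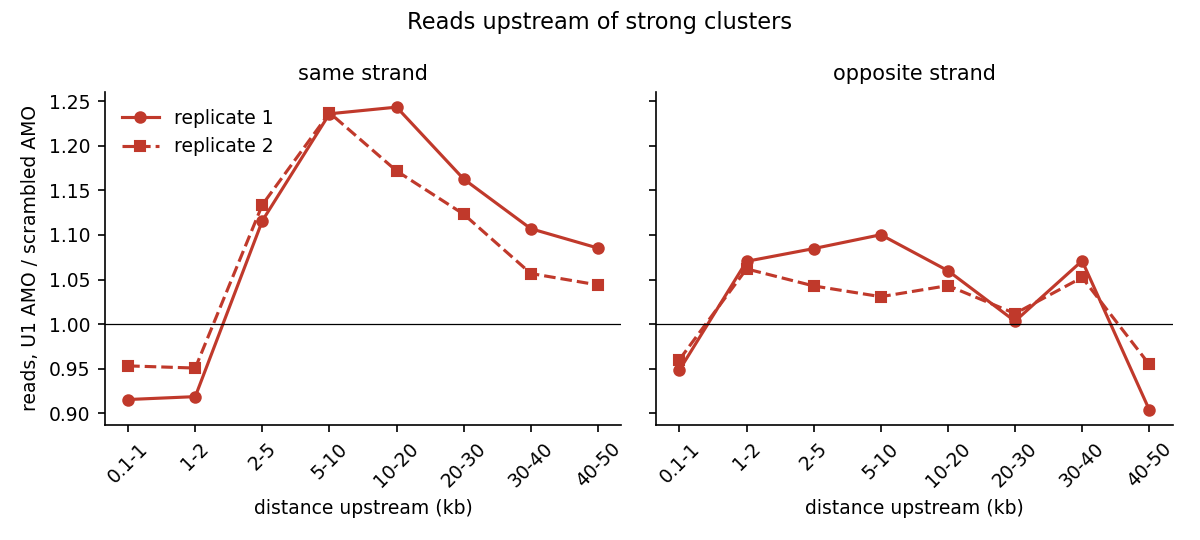
Ratio of CPM, U1 AMO to scrambled AMO, by distance upstream (kb) of 6433 strong clusters on the same and the opposite strand; each line is the pair of libraries of one run. On the same strand the ratio is 1.24 in both runs at 5 to 10 kb, and 0.916 and 0.953 within 1 kb.

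More distinct positions were counted with the U1 AMO than with the scrambled AMO at equal depth. After thinning to 15752080 reads there were 663114 ± 28950 distinct positions with the U1 AMO, 584390 ± 51808 with the scrambled AMO and 442776 ± 106098 in untreated cells (SD, n = 2). The ratio of U1 AMO to scrambled AMO was 1.13, and 1.10 and 1.17 within the runs. The exact permutation p was 0.333, the smallest possible. Thinning equalises reads and not molecules, so the number of molecules captured per library can also move these counts. It was not measured. The 2 untreated libraries alone had 517798 and 367754 positions. Clusters with at least 2 reads numbered 98092 with the U1 AMO, 83098 with the scrambled AMO and 86689 in untreated cells (means).

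**Figure D4:**
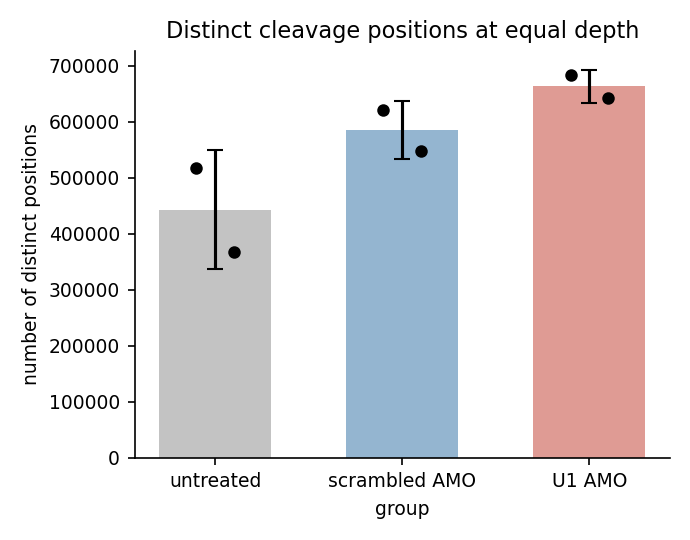
Distinct cleavage positions per library after thinning to 15752080 reads; bars are group means, error bars the SD and points the 2 libraries of each group. Both U1 AMO libraries lie above both scrambled AMO libraries, at 683584 and 642643 positions against 621024 and 547756.

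The share of reads with a common poly(A) signal was similar in the 3 groups. All signal shares given here leave out chromosome M. AATAAA or ATTAAA, the most common signals, accompanied 87.8% ± 0.501 of reads with the U1 AMO, 87.5% ± 0.462 with the scrambled AMO and 87.8% ± 0.121 in untreated cells (SD, n = 2; exact permutation p = 0.667 for U1 AMO against scrambled AMO). Within the runs the U1 AMO share was higher by 0.256 and 0.201 percentage points. Counted over distinct positions, the shares were 63.5% ± 5.09 with the U1 AMO, 60.9% ± 3.27 with the scrambled AMO and 63.5% ± 0.890 in untreated cells (SD, n = 2; exact permutation p = 0.667), and the U1 AMO was higher by 3.92 and 1.34 points within the runs. For reads, leaving out scrambled AMO replicate 2 or U1 AMO replicate 1 turned the difference of means to -0.0983 and -0.125 points. Among raised clusters 76.0% had one of these signals at the strongest position, against 69.8% of matched uncalled clusters (Fisher's exact test over clusters, p = 0.00407). AATAAA alone was at 52.9% against 52.2% (Fisher's exact p = 0.812), so the excess of these 533 lay in ATTAAA. Clusters that rose in the fit with run as a term had either signal at 74.9% against 60.6% of their matched clusters and AATAAA alone at 53.2% against 45.6% (Fisher's exact p = 1.10e-93 and 1.42e-24). Among the 533 the hexamer AAAAAA was found at 0.188% against 2.63% (Fisher's exact p = 6.52e-05).

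The second comparison asked what delivery of a morpholino does without targeting U1. No cluster differed between the scrambled AMO and untreated cells in the edgeR test, with 10490 clusters at an unadjusted p under 0.05 (6818 higher and 3672 lower). DESeq2 called 1371 higher and 885 lower, and edgeR without the filter on low counts called 1100 and 179. Leaving U1 AMO replicate 1 out of the shared fit, chosen after seeing the data, gave 20 higher and 2 lower. These groups were sequenced in different runs. Changes of 4-fold were recovered in 4% of cases in simulated counts, so differences of that size were mostly not detectable.

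The third comparison set the U1 AMO against untreated cells. Here 3512 clusters rose and 404 fell in edgeR. The cluster at chr14:52700835-52700854 (minus strand) had 66.1 ± 1.73 CPM (SD, n = 2) with the U1 AMO and no reads in either untreated library, at least 2160-fold higher against a floor of 3 counts over the group. The clusters at chr2:128929801-128929811 (plus), chr4:153353347-153353374 (plus), chr10:88288888-88288904 (minus) and chr12:21419256-21419269 (minus) likewise had no untreated reads and were at least 2030-fold, 1869-fold, 1413-fold and 1463-fold higher.

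The falls were largely shared with the scrambled AMO, but the rises were shared only in small part. All 404 lowered clusters were below both untreated libraries in both scrambled AMO libraries. Of the 3512 raised clusters, 2038 (58.0%) were above both untreated libraries in both scrambled AMO libraries. An untreated level of 0 makes any scrambled AMO read meet this order, so no chance share is set beside it. Over the 3512 the median levels were 0 and 0 CPM in untreated cells, 0.112 and 0.0803 with the scrambled AMO, and 2.48 and 1.84 with the U1 AMO. The cluster at chr11:87369318-87369328 (plus strand) had 5.94 ± 0.856 CPM with the U1 AMO, 5.55 and 7.47 in the scrambled AMO libraries and 51.0 ± 13.5 in untreated cells (SD, n = 2), with a log2 fold change of -3.12 ± 0.39 (SE) for U1 AMO against untreated and an adjusted p of 0.0176 in edgeR. At chr7:6656576-6656619 (minus) the means were 42.5 CPM with the U1 AMO and 277.9 in untreated cells, with 63.3 and 32.3 in the scrambled AMO libraries. The log2 fold changes at chr2:34749270-34749307 (minus), chr8:96662925-96662941 (plus) and chr8:47082240-47082272 (minus) were -3.05, -2.83 and -2.76. Over the 404 clusters the median levels were 21.9 and 28.5 CPM in untreated cells, 8.75 and 7.91 with the scrambled AMO, and 6.32 and 6.56 with the U1 AMO. These clusters were selected for high levels, and the raised ones for low levels, in the same untreated libraries. Both sets were also selected on their levels in the same U1 AMO libraries.

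Untreated libraries came from other runs than the AMO libraries, so a part due to run cannot be separated from treatment in this comparison. The scrambled AMO libraries shared the runs of the U1 AMO libraries. Over the 3512 rises their median levels were 0.112 and 0.0803 CPM, against 2.48 and 1.84 with the U1 AMO. The 3512 clusters were called from the same U1 AMO libraries, which favours a gap in this direction. The medians therefore cannot settle how much of those rises is due to run. For the 404 falls the AMO groups had similar levels, and treatment and run cannot be told apart. The calls numbered 8778 without untreated replicate 1, 1850 without untreated replicate 2, 1013 without U1 AMO replicate 2 and 1393 in a fit of the 4 libraries alone. With the replicate number as a block there were 0 by edgeR (16724 at an unadjusted p under 0.05), and DESeq2 without a block called 10187.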

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

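Tests with run as a term in 4 libraries, crossed numbers, library size alone, a robust fit, thinning, chromosome M left out, the 0-to-10 value at 5 or less, clusters counted in place of positions, and leaving out a library of the group outside the comparison were chosen only after seeing the data. For U1 AMO against scrambled AMO, the 533 calls became 3129 with DESeq2, 2912 without the low-count filter, 2599 with the 4 libraries alone, 842 with clusters of at least 2 positions, 920 after thinning and 0 with the replicate number as a block in 6 libraries. With run as a term they became 10770, or 6080 after thinning, 10332 without chromosome M, 11232 with RLE factors and 10563 with library size alone. Leaving out a library gave 0 to 1157 within the groups compared and up to 2951 for an untreated one. No call was lowered in these alternatives except 15 without the filter, 1571 with run as a term, 886 with thinning added, 1406 without chromosome M, 2213 with RLE and 1295 with library size. RLE factors (711), a robust fit (732), library size alone (577), joining at 100 nt (547) and the 0-to-10 value at 5 or less (737) stayed within 1.5 times the main count. The limit on the 0-to-10 value left only 44030 clusters to test, and 340 of its calls were among the 533.

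Scrambled AMO against untreated gave 2256 calls with DESeq2, 1279 without the filter, 22 without U1 AMO replicate 1 and 0 in the other alternatives. U1 AMO against untreated had 3916 calls, 10187 with DESeq2, 7175 without the filter, 1393 with the 4 libraries alone, 0 with the replicate block in 6 or in 4 libraries, and 1013 to 8778 without one library. Untreated numbers deviated against the AMO numbers (r = -0.42 with scrambled, -0.36 with U1); crossing them in the block gave 1729, 0 and 9036 calls in the order of the report. With a library left out, its group's lone library is assumed to vary like the other groups.

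The downstream arrangement turned to 30.8% of raised clusters at 10 kb and the divergent one fell to 8.44% at 2 kb; the cause was not tested. Leaving out a library of any group gave 74.2% to 80.2% downstream, 19.8% to 36.4% divergent and 3.03% to 7.79% convergent; without scrambled AMO replicate 2 there was no call to place. The ratio of distinct positions was 1.07 to 1.21 without one library. The signal share differed by 0.279 points for AATAAA only, 2.63 for positions, and -0.125 to 0.582 without one library. For clusters named from the 6-library fit no direction changed; the call was lost in 15 tests with the block in 6 libraries, 11 in fits of 4 libraries and 15 with a library left out. For the 6 falls named from the fit with run as a term, 20 alternative tests, all with run as a term, kept the call, and 72 lost it. Fits with a library left out had no run term, and the 6-library fit without it called none of these falls. They compare libraries across runs, so they cannot show whether a fall within runs rests on one library. In them 8 log2 changes turned direction. Leaving out one library gave log2 changes of -8.45 to 1.55 (chr4:68759744), -8.40 to 1.85 (chr4:40290052), -5.11 to 0.47 (chrX:119879536), -6.56 to 1.45 (chr16:11262290) and -7.79 to 1.94 (chr2:76889896). Results needing an mm9 annotation were not run. Depth leaves folds as bounds or wide intervals where scrambled AMO counts are at most 3 (204 of the 533).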

Other observations

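Tests of depth, normalization, runs of clusters and chromosome M were chosen only after the result was seen. Part of the clusters raised by the U1 AMO lay in runs along one strand. Of 9163 clusters outside chromosome M that rose in the fit with sequencing run as a term, 2113 (23.1%) lay in 324 same-strand runs of at least 5 raised clusters with gaps of at most 50 kb, and 2757 were single. The run with most, 20 clusters, spanned chr10:117117411-117255771 on the minus strand (mm9) and summed to 452.8 and 300.1 CPM with the U1 AMO against 169.7 and 87.7 with the scrambled AMO. The next, 17 clusters at chr8:87551646-87621500 on the plus strand, had 110.8 and 87.7 CPM against 37.4 and 35.4. At chr8:8656485-8682761 on the minus strand, 16 had 482.7 and 465.0 against 303.2 and 324.9. At chr8:46021195-46079915 on the plus strand, 16 raised clusters summed to 57.9 and 63.0 CPM with the U1 AMO, against 1.15 and 0.996 with the scrambled AMO and 0.519 and 0.562 in untreated cells. At chr6:119884836-119986466 on the minus strand, 14 raised clusters summed to 18.3 and 10.7 CPM against 0.670 and 0.675 with the scrambled AMO. At chr19:36913673-36994444 on the plus strand, 13 summed to 39.0 and 34.7 CPM against 3.24 and 2.99. The other listed runs were 14 clusters at chr12:66069156-66195242 (plus), with 112.2 and 107.0 against 48.1 and 63.4, and 13 at chr5:115687424-115795677 (minus), with 1231 and 881.2 against 802.7 and 685.2. These regions were chosen for their number of raised clusters, and no comparison with chance was made.

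More clusters were raised than lowered by the U1 AMO, and the absence of lowered calls in the 6-library fit says little, since that fit rarely detects falls of the size seen with run as a term. Priming inside A-rich sequence was weighed on a prediction written before the test. AAAAAA was at 0.188% of raised and 2.63% of matched clusters, and AATAAA or ATTAAA at 76.0% (interval 72.2% to 79.4%) against 69.8% (68.0% to 71.5%). The pattern predicted for such priming was not seen in these shares. They cannot rule such priming out, because every listed position carried a hexamer and the sequence beyond the clusters was not examined. AATAAA alone was at 52.9% against 52.2% (Fisher's exact p = 0.812), so the excess of the 533 lay in ATTAAA, while clusters raised with run as a term had AATAAA at 53.2% against 45.6% (p = 1.42e-24, Fisher's exact) and AAAAAA at 0.939% against 5.52%; the genome sequence around the clusters was not used here. With run as a term, 85.4% of calls were raised after thinning to one depth, 87.7% with library size alone and 80.3% with RLE factors. Most calls were thus still rises at equal depth and under each scaling. The condition written for normalization, after the result was seen, asked among other things that all calls stay raised without TMM. This fit did not meet it, with 1295 falls with library size alone, and the 6-library fit called no falls under any scaling. A bound of 75% was set for normalization after similar shares were known, so passing it decides nothing. Loss of U1 activity remains a hypothesis, and differences between the AMO sequences other than their target were not tested.

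A hypothesis set before the test was that the U1 AMO raises cleavage more on the arm of a divergent pair that has a stronger same-strand cluster downstream than on the arm that has none. In 1249 such pairs within 5 kb the median difference of log2 fold changes, on CPM plus 0.5, was 0.081 (95% bootstrap interval 0.031 to 0.121) in replicate 1 and 0.053 (0.017 to 0.093) in replicate 2, between arms of 0.541 and 1.16 median CPM. In 328 pairs with arms within 2-fold of each other it was smaller, 0.066 (-0.023 to 0.165) in replicate 1 and 0.026 (-0.040 to 0.147) in replicate 2; with run as a term it went from 0.111 to 0.088 (-0.060 to 0.187). The difference was close to 0 in 734 pairs within 2 kb, 0.013 (-0.054 to 0.069) and 0.010 (-0.032 to 0.049), and in 1106 pairs with a downstream limit of 10 kb, -0.010 (-0.057 to 0.069) and 0.014 (-0.025 to 0.047). Of the limits tried, it was seen only at 5 kb for the pair with 50 kb downstream, and there an effect of the downstream cluster and one of arm abundance cannot be told apart, because the intervals of the 328 pairs hold both 0 and the full difference.

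A further hypothesis set before the test was that strong clusters fall where a raised cluster lies upstream on the same strand. The median log2 fold change was -0.15 for 4220 strong clusters with a raised cluster within 50 kb upstream and -0.16 for 4102 matched strong clusters without one. The difference was 0.017 (95% bootstrap interval 0.004 to 0.030) with run as a term, 0.018 (-0.001 to 0.034) in replicate 1 and 0.028 (0.016 to 0.037) in replicate 2, so the predicted fall was not seen.

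The share of reads on chromosome M was 0.617% and 0.352% in untreated cells, 1.60% and 0.853% with the scrambled AMO and 2.15% and 1.22% with the U1 AMO, with ratios of U1 AMO to scrambled AMO of 1.34 and 1.43 within the runs (exact permutation p = 0.667 across groups).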
